A study of Homo sapiens with 6 samples.

How the data were processed

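RNA-seq counts and normalized values were analysed for 6 libraries of the NCI-H226 cell line, 3 labelled shNSUN4 and 3 labelled shControl. Groups and replicate numbers came from the sample titles. The table's columns for the controls carry that word and a number, and the other 3 columns (SH with a number) were matched to the shNSUN4 titles. Per the labels' protocols, total RNA was made into libraries with a low-input RNA kit. The submitters' processing notes name cutadapt 1.9.3, HISAT2 2.0.4, HTSeq 0.9.1, edgeR 3.16.5 and genome build hg19, without their roles. The annotation release, the strand setting and the handling of reads with several matches are not given in the sources used here.

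The authors' deposited table holds raw read counts per gene, per the file headers, for 15515 genes, all protein coding and each with at least 1 count over the libraries. 19 symbols stand on more than 1 gene ID, and 0 rows name no gene. The authors also deposited normalized log2 values, which they made with edgeR, per the file headers. They equal log2 CPM: recomputed from the counts with TMM (trimmed mean of M-values) factors and a prior count of 2, the largest difference was 4.99e-09. These log2 values were used only for that check. Every result comes from the counts.

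The total count per library ran from 6915804 to 13282414, with 8166793, 6915804 and 8274354 for shNSUN4 and 13282414, 12949116 and 12930652 for shControl. The 10 most abundant genes took 3.68%, 3.67% and 3.73% of the counts for shNSUN4 and 4.36%, 4.32% and 4.25% for shControl. Within a group, no pair of libraries agreed within sampling noise: chi-square per degree of freedom ran from 4.22 to 10.2 over genes with at least 20 counts in the pair. The interval of the NSUN4 fold change comes from the quasi-likelihood fit and includes the spread between libraries; floors and the intervals of count ratios cover counting error only.

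Genes were kept by edgeR's filterByExpr, which left 11898. Libraries were scaled by TMM, and the 2 groups were compared with edgeR 4.0.16 (quasi-likelihood F test, robust, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.122. Standard errors are the log2 fold change divided by the square root of F. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts the ratio has an exact binomial 95% interval. Gene lists (28, with 27 tested) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Members were matched by symbol; a symbol on several IDs was read from the ID with the most counts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

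The tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes NSUN4 and MTERF4, the mitochondrial rRNAs where measured, the 12 largest rises and the 12 largest falls, the 5 genes with the smallest p, and up to 4 members with the smallest adjusted p from each list called or with at least 3 called members. The largest changes were taken among genes with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group, no overlap between the groups, and a symbol that is not a locus, clone or small RNA name. Members of lists are named from these 4, except where the text says that they were named after their values were seen. Some genes that the rule takes are not reported here.

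The procedure was tested on simulated data drawn from the means, dispersions and depths of the 11898 genes for the comparison of shNSUN4 with shControl. It recovered 18% of genes changed 1.25-fold, 50% of those changed 1.5-fold, 80% of those changed 2-fold and 94% of those changed 4-fold (50 genes each). Of 123 genes called there, 2 were false. Far fewer genes were changed there than the 5114 called in the data, which makes the adjustment for multiple tests stricter. The shares recovered may therefore understate those in the data. In a second simulation, 1 list was shifted by a factor of 1.3, and camera called it and 0 of the other lists. Genes were drawn independently there, whereas in the data the estimated correlation within a list was, for instance, 0.26 for histones. The simulation therefore does not show how camera behaves where members vary together.

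Alternatives were other scalings (DESeq2's size factors, upper quartile, library sizes alone), no filter (at least 1 count), a stricter filter (10 counts in 3 libraries and a mean of 1 CPM), DESeq2 1.42.0, limma-voom, no robust fit, the replicate number as a block, and leaving out each library. Others were an adjusted p of 0.01, a 2-fold minimum, a test against a fold of 1.2, and an estimated correlation or fry for lists. Added after the data were seen were a correction for GC content and transcript length (a loess per library, used as an offset), libraries thinned to equal depth, list members matched by current symbol, and a test of the KEGG pathway names in the deposited table. Length and GC content came from GENCODE v29 transcripts for 15399 of 15515 genes. That release is on GRCh38, another build than the counts, so no coordinates are printed.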

Results

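RNA-seq was carried out on NCI-H226, an established human lung carcinoma cell line of pleural origin that is often classed as mesothelioma. The labels describe cells carrying an shRNA against NSUN4 and cells carrying a control shRNA. NSUN4 is a mitochondrial methyltransferase of the small-subunit rRNA, and in a complex with MTERF4 it serves the assembly of mitochondrial ribosomes. There were 3 libraries labelled shNSUN4 and 3 labelled shControl, numbered 1 to 3 in each group. Total counts over 15515 protein-coding genes were 8166793, 6915804 and 8274354 in the libraries labelled shNSUN4. They were 13282414, 12949116 and 12930652 in the libraries labelled shControl, so that depth differed between the groups. No label says whether the libraries came from separate cultures or from different shRNAs. The p-values below therefore measure only the spread between these libraries, which may be technical.

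The stated purpose was to learn what NSUN4 does in these cells by knocking it down, so the targeted gene was examined first. NSUN4 (ENSG00000117481) was not lower in the libraries labelled shNSUN4. They held 21, 32 and 33 NSUN4 counts, against 43, 29 and 31 counts in the deeper control libraries. After scaling, NSUN4 stood at 3.75 ± 1.05 CPM (read count scaled to library size; SD, n = 3) against 2.62 ± 0.53 CPM (SD, n = 3) in the libraries labelled shControl. The log2 fold change was 0.51 (SE 0.47, 95% interval -0.45 to 1.47), a fold of 1.43 with an interval from 0.733 to 2.77. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave an adjusted p of 0.41. A two-sided exact permutation test gave p = 0.2, where 3 against 3 libraries can give no p below 0.1. A change of the targeted gene was thus not shown in either direction. Because the fall that the label implies was not seen, the groups are called by their labels throughout. Every direction below is that of the libraries labelled shNSUN4 relative to those labelled shControl. MTERF4, listed under its older symbol MTERFD2, stood at 31.8 ± 3.75 against 37.0 ± 2.89 CPM (SD, n = 3 each), with a log2 fold change of -0.22 and an adjusted p of 0.22 in edgeR. The mitochondrial rRNAs were not analysed here.

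**Figure D1:**
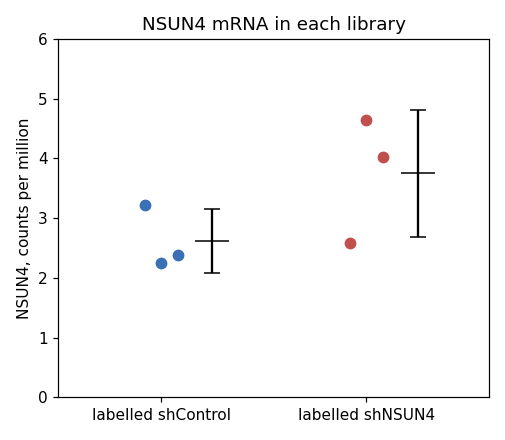
NSUN4 CPM in each of the 6 libraries (points), with the mean and SD of each group (bar and whiskers, n = 3). The libraries labelled shNSUN4 lie between 2.58 and 4.64 CPM and those labelled shControl between 2.24 and 3.23 CPM, so the groups overlap.

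The libraries of both labels nevertheless differed in a large part of the transcriptome. Of 11898 genes tested, 5114 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 2619 of them higher and 2495 lower in the libraries labelled shNSUN4. With upper-quartile scaling the balance turned, to 2287 higher and 2891 lower. A change of at least 2-fold was found in 1406 of the called genes, of which 579 were higher and 827 lower. The values of both groups did not overlap in 6116 genes, or 51.4% of those tested, where chance gives 10%. Among the largest rises was IL13RA2, a decoy receptor for interleukin-13, which had 147 counts over the libraries labelled shNSUN4 and 0 over the controls and was thus at least 82.8-fold higher. ESM1, a secreted proteoglycan, rose from 0.610 ± 0.333 to 40.9 ± 3.02 CPM (SD, n = 3 each). SCN3A, a sodium channel, had 132 counts against 2, a ratio of 111.6 with a 95% counting interval from 30.3 to 931. Other genes in this set were SUN3, PKIA, PAPL, NGFR, ACTN2, PRICKLE2, HECW2 and FAM196B, with log2 fold changes from 5.76 (SUN3) to 4.11 (FAM196B). Without shControl replicate 3, SUN3 moved to 6.92, with 1 control count left, and PAPL from 4.78 to 5.98, with 5 left; without shControl replicate 2, SCN3A had 0 control counts.

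Among the largest falls, GKN1 had 198 counts in the libraries labelled shControl and 0 in those labelled shNSUN4, at least 39.0-fold lower. MGARP, a mitochondrial protein, had 401 counts against 1, a ratio of 237.2 with a counting interval from 42.3 to 9391. HSD3B1, an enzyme of steroid hormone synthesis, fell from 130.1 ± 5.64 to 1.12 ± 0.675 CPM (SD, n = 3 each), and POSTN, the matrix protein periostin, from 91.5 ± 7.15 to 1.38 ± 0.487 CPM (SD, n = 3 each). FGFBP1, CFI, ITLN2, PTPRQ, NOX1, SLCO2A1, CRB2 and BCAS1 made up the rest, with log2 fold changes from -7.40 (FGFBP1) to -6.05 (BCAS1). With 1 to 4 counts left in the libraries labelled shNSUN4, CFI (-8.07) and PTPRQ (-7.66) moved from -7.10 and -6.70 without shNSUN4 replicate 2, NOX1 (-7.88) and SLCO2A1 (-7.385) from -6.63 and -6.52 without shNSUN4 replicate 1, and CRB2 (-7.67) and NOX1 (-6.04) from -6.24 and -6.63 without shNSUN4 replicate 3. MGARP had 0 counts there without shNSUN4 replicate 1, and ITLN2 without shNSUN4 replicate 2. The smallest p-values belonged to abundant genes. ALDH1A3, which makes retinoic acid, fell from 6285 ± 157 to 566 ± 12.8 CPM (SD, n = 3 each), and KIAA1199, a hyaluronan-binding protein, fell by 5.11 on the log2 scale. PTGIS, the prostacyclin synthase, fell by 5.60 on the log2 scale. MME, the membrane peptidase neprilysin, rose from 192 ± 9.63 to 2553 ± 31.9 CPM (SD, n = 3 each), and HMGA2, a chromatin protein, had a log2 fold change of 3.58. The adjusted p of these 5 genes in edgeR ran from 9.39e-40 to 7.22e-36. Across genes, which are not independent replicates, the log2 fold change declined with the GC content of the transcript (Spearman rho -0.357), from a median of 0.22 in the fifth of genes with the lowest GC content to -0.35 in the highest. Relative to each gene's mean over the 6 libraries, genes of that highest GC group had medians of -0.11, -0.20 and -0.17 in the libraries labelled shNSUN4 and of 0.33, 0.11 and 0.13 in those labelled shControl.

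Markers of mesothelium, the cell layer that lines the pleura, were lower as a group. Of 18 measured markers, 17 fell and 0 rose, with a median log2 fold change of -1.86 (the same counts when adjusted over the list alone). KRT18, KRT8 and KRT7, keratins of simple epithelia, fell by 2.02, 1.82 and 1.91 on the log2 scale. UPK1B, a uroplakin, fell by 2.27 on the log2 scale, and KRT7 stood at 474.6 ± 23.5 against 1778 ± 147 CPM (SD, n = 3 each). The list passed camera, which compares a list with all other genes, with an adjusted p of 5.79e-10 at its preset correlation, and had an adjusted p of 0.0889 with an estimated correlation. Genes of cholesterol synthesis and uptake were also lower. Of 23 measured members, 21 fell and 1 rose (also adjusted over the list alone), with a median log2 fold change of -1.25. HMGCS1, which makes the precursor of mevalonate, fell from 700.4 ± 43.7 to 244 ± 9.60 CPM (SD, n = 3 each). DHCR7, a late enzyme of the pathway, fell by 2.05 on the log2 scale and MSMO1 by 1.25. The camera test gave an adjusted p of 1.07e-09, and an adjusted p of 0.0536 with an estimated correlation.

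**Figure D2:**
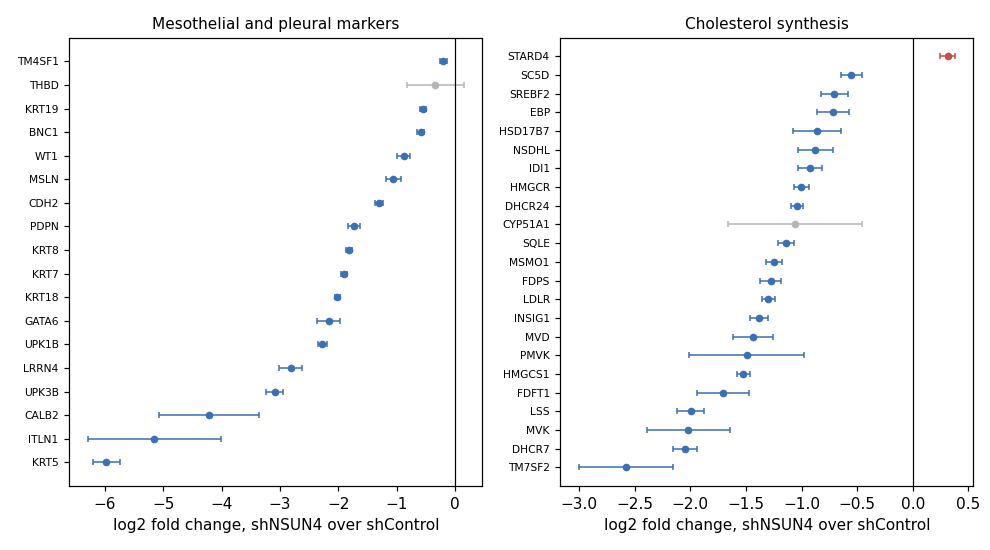
Log2 fold change of each measured member of the mesothelial list (left, 18 genes) and the cholesterol synthesis list (right, 23 genes), libraries labelled shNSUN4 over those labelled shControl (n = 3 each). Points are estimates and whiskers standard errors. Blue marks genes called lower, red genes called higher and grey genes not called; 17 mesothelial and 21 cholesterol genes are blue.

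The lists for DNA replication, mitosis and histones were called lower. In the list for G1/S and DNA replication, 31 of 45 measured members fell and 1 rose (34 and 1 adjusted over the list alone). MCM2 and MCM7, subunits of the replicative helicase, fell by 1.34 and 1.09 on the log2 scale, and UNG, a uracil-DNA glycosylase, by 1.80. CCND1, which encodes cyclin D1, was the 1 member that rose, from 552 ± 25.2 to 1115 ± 20.4 CPM (SD, n = 3 each). The camera adjusted p was 1.02e-07 (adjusted p = 0.112 with an estimated correlation). In the G2/M and mitosis list, 20 of 46 members fell and 4 rose, the same counts adjusted over the list alone; after a correction for GC content and length, added after the data were seen, 25 fell and 1 rose. KIF20A, a mitotic kinesin, fell by 1.26 on the log2 scale, MKI67 by 0.60 and ASPM by 0.49. The camera adjusted p was 0.00895, and the adjusted p was 0.605 with an estimated correlation. The KEGG cell cycle set, tested after the data were seen, held 24 genes higher and 34 lower of 117 and was not called (adjusted p = 0.625). Replication-dependent histones fell in 30 of 41 measured genes and rose in 0 (32 and 0 adjusted over the list alone), with a median log2 fold change of -0.69. Examples were HIST1H3H, which fell by 1.41, and HIST1H2BF, which fell by 0.97 on the log2 scale; near-identical copies can share reads, so single histone genes are uncertain. The camera adjusted p for histones was 6.48e-08 (adjusted p = 0.338 with an estimated correlation). Their transcripts had a median GC content of 57.4% against 49.5% for all genes tested, and after the GC and length correction their median log2 fold change was -0.43.

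Several lists of stress response genes were higher. In the list for the integrated stress response through ATF4, 16 of 35 measured members rose and 3 fell (the same adjusted over the list alone), and 22 rose and 0 fell after the GC and length correction. SLC7A11, the cystine transporter, rose from 103 ± 7.38 to 715 ± 24.2 CPM (SD, n = 3 each). ATF3, a stress-induced transcription factor, had a log2 fold change of 2.14, GDF15, a secreted stress cytokine, of 1.44 and GARS, a tRNA synthetase, of 0.78. The camera adjusted p was 0.000454, and the adjusted p was 0.291 with an estimated correlation. Of 19 measured immediate early genes, 11 rose and 0 fell (the same adjusted over the list alone), among them PHLDA1 (log2 fold change 2.02), DUSP5 (2.91), a phosphatase of ERK, and FOSL1 (1.59). This list had an adjusted p of 7.87e-05 in camera (adjusted p = 0.291 with an estimated correlation). It shares ATF3 with the list for the integrated stress response, so these lists are not fully separate. Of 35 measured p53 targets, 18 rose and 4 fell (19 and 4 adjusted over the list alone). PMAIP1, the pro-apoptotic protein NOXA, had a log2 fold change of 3.96, and MDM2, which targets p53 for degradation, of 0.75. The p53 list had an adjusted p of 0.0113 in camera (adjusted p = 0.37 with an estimated correlation). For p53 signaling, the KEGG set tested after the data were seen held 20 genes higher and 10 lower of 56. That set was not called (camera adjusted p = 0.434, direction up).

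The unfolded protein response of the endoplasmic reticulum and the hypoxia and glycolysis list were called by a narrow margin. In the former, 11 of 23 members rose and 2 fell (the same adjusted over the list alone). HSPA5, the main chaperone of that compartment, had a log2 fold change of 0.96, and EDEM1 of 0.79. Its camera adjusted p was 0.0436 (adjusted p = 0.291 with an estimated correlation), and became 0.0813 with the replicate number as a block, 0.0659 without the library labelled shNSUN4 replicate 1 and 0.101 without shControl replicate 3. Tested after the data were seen, the KEGG set for protein processing in this compartment held 45 genes higher and 24 lower of 134. That set was not called (camera adjusted p = 0.426, direction up). In the hypoxia and glycolysis list, 15 of 31 members rose and 9 fell (the same adjusted over the list alone). HK2, which starts glycolysis, rose from 98.9 ± 6.78 to 476 ± 12.4 CPM (SD, n = 3 each), with NDRG1 at a log2 fold change of 1.97 and PDK1 at 0.92. Its camera adjusted p was 0.045 (adjusted p = 0.605 with an estimated correlation), and became 0.0698 with the replicate number as a block, 0.0656 without shControl replicate 2 and 0.0994 without shControl replicate 3. The 9 that fell, named after their values were seen, were ADM and the glycolytic enzymes GAPDH, PFKL, PKM, ENO1, ALDOA, GPI, ALDOC and TPI1. The KEGG set for glycolysis and gluconeogenesis, tested after the data were seen, held 6 genes higher and 15 lower of 40 and was not called (adjusted p = 0.547, direction down). The lysosome and autophagy list was not called (adjusted p = 0.0606), although 10 of its 29 members rose and 3 fell, including WIPI1 (log2 fold change 2.12) and MAP1LC3B (0.77). After the GC and length correction it was called higher, with 12 members up and 1 down (adjusted p = 0.00713, or adjusted p = 0.279 with an estimated correlation).

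Interferon-stimulated genes moved in both directions. Of 42 measured members, 13 rose and 22 fell (13 and 24 adjusted over the list alone). RSAD2, the antiviral enzyme viperin, rose from 18.2 ± 0.866 to 218 ± 25.8 CPM (SD, n = 3 each), and OASL and IFIT2 had log2 fold changes of 3.55 and 2.09. MX1, an antiviral GTPase, fell from 174 ± 11.2 to 33.0 ± 4.06 CPM (SD, n = 3 each). The list as a whole was not called by camera (adjusted p = 0.307, direction down), whereas fry, which does not compare a list with other genes, gave the direction up with an adjusted p of 0.033. Antigen presentation by MHC class I was lower, with 9 of 16 members down and 0 up, the same counts adjusted over the list alone. TAPBP, the peptide-loading factor tapasin, fell by 0.70 on the log2 scale, and the immunoproteasome subunit PSMB8 fell by 1.08. Its camera adjusted p was 0.00895, and the adjusted p was 0.291 with an estimated correlation. The median GC content of its members was 56.2%, and the median log2 fold change of -0.49 became -0.30 after the GC and length correction. A KEGG set for antigen processing and presentation, tested after the data were seen, held 7 genes higher and 13 lower of 30. That set was not called (camera adjusted p = 0.434, direction down). In the list of NF-kB targets and inflammatory cytokines, 8 of 28 rose and 13 fell. CCL5 rose from 3.23 ± 1.51 to 36.5 ± 3.59 CPM and CCL2 fell from 102 ± 9.60 to 13.8 ± 1.94 CPM (SD, n = 3 each). The list was not called (adjusted p = 0.247), and its median of -0.19 and mean of 0.25 differ in sign. After the GC and length correction the median turned to 0.0136, with 6 higher and 10 lower.

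**Figure D3:**
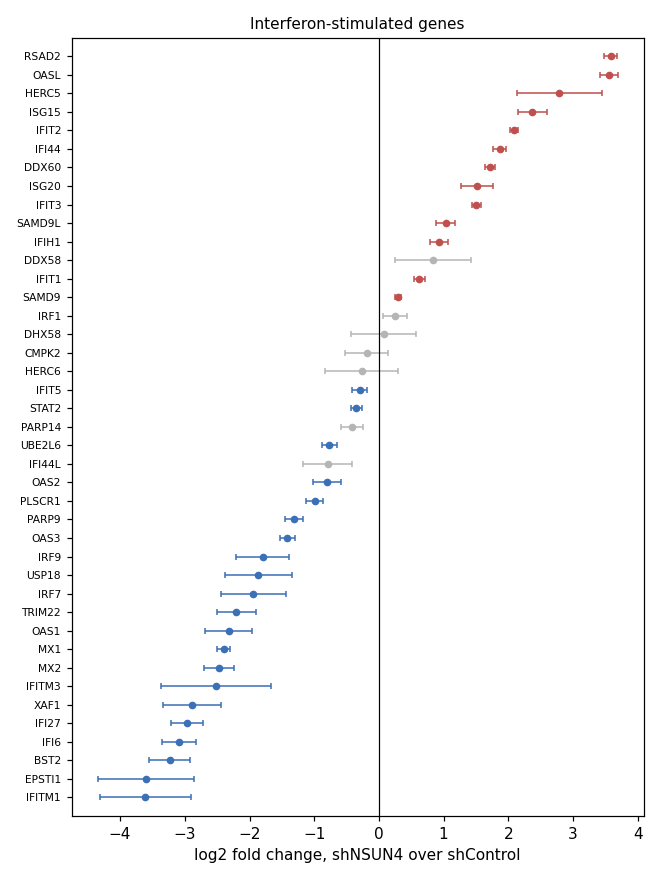
Log2 fold change of measured interferon-stimulated genes (all but 1 of the 42), libraries labelled shNSUN4 over those labelled shControl (n = 3 each). Points are estimates and whiskers standard errors, red for genes called higher, blue for genes called lower and grey for those not called. The 13 red points include RSAD2 and OASL, and MX1 is among the blue ones.

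Lists of mitochondrial genes were examined because NSUN4 acts in mitochondrial gene expression. Of 13 listed mitochondrially encoded mRNAs only 5 were measured, so this list covers a part of them. Among the 5, 2 rose and 0 fell, with a median log2 fold change of 0.12. After the GC and length correction 0 rose and 1 fell. Of 73 mitochondrial ribosomal proteins, 5 rose and 8 fell (3 and 2 adjusted over the list alone, 3 and 7 after that correction, where the median turned from -0.0039 to 0.0137), with MRPS35 at a log2 fold change of 0.44 and MRPS9 at -0.62. Of 29 mitochondrial rRNA and translation factors, 5 rose and 2 fell (3 and 1 adjusted over the list alone, 2 and 0 after that correction). METTL15, a methyltransferase of the mitochondrial small-subunit rRNA, rose from 39.0 ± 2.48 to 60.1 ± 3.51 CPM (SD, n = 3 each). Of 76 nuclear subunits of oxidative phosphorylation, 3 rose and 17 fell (2 and 14 adjusted over the list alone), with ATP5D, a subunit of ATP synthase, at a log2 fold change of -1.12. Among 17 mitochondrial chaperones and proteases, 3 rose and 5 fell, the chaperone HSPA9 with a log2 fold change of 0.41 and TRAP1 with -0.49. None of these 5 lists was called, with camera adjusted p-values of 0.561, 0.852, 0.982, 0.128 and 0.484 in that order. For the rRNA and translation factors the median (-0.05) and mean (0.02) differ in sign. Cytosolic ribosomal proteins were lower, with 46 of 73 down and 3 up (47 and 3 adjusted over the list alone) and a median log2 fold change of -0.20. RPL6 fell by 0.56 and RPS2 by 0.65 on the log2 scale. Their camera adjusted p was 0.000242 (adjusted p = 0.291 with an estimated correlation); pseudogenes of these genes can share reads with them.

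The remaining lists held called genes in both directions and were not called as lists on the uncorrected values. Among epithelial-mesenchymal and matrix genes, 12 of 38 rose and 19 fell (13 and 19 adjusted over the list alone). ITGA5, an integrin chain, had a log2 fold change of 1.35, SPARC of -1.11 and TPM1 of -1.47. Of 26 targets of YAP and TEAD, 7 rose and 11 fell. NT5E, a surface nucleotidase, rose from 319 ± 5.01 to 1187 ± 20.6 CPM (SD, n = 3 each), and CRIM1 fell by 0.92 on the log2 scale. Of 23 TGF-beta targets, 4 rose and 9 fell (5 and 9 adjusted over the list alone), with ID2 at -3.15 and FN1 at -1.45 on the log2 scale. Of 23 NRF2 and glutathione targets, 9 rose and 10 fell, with NQO1 at 0.58 and TKT at -0.68. Among 5 squamous and airway markers, 2 rose and 2 fell. The fall of KRT5 from 68.3 ± 4.12 to 1.05 ± 0.586 CPM (SD, n = 3 each) counts there and among the mesothelial markers. Of 13 writers, readers and erasers of 5-methylcytosine, 3 rose and 3 fell, with TET3 at 0.57 and DNMT1 at -0.58. Of 31 R-loop and DNA damage factors, 3 rose and 7 fell, with RPA1 at -0.40 and FANCD2 at -0.53. After the GC and length correction 0 of these rose and 9 fell, and that list was called lower (adjusted p = 0.0429, or adjusted p = 0.246 with an estimated correlation). Camera adjusted p-values for these 7 lists were 0.245, 0.736, 0.361, 0.586, 0.901, 0.799 and 0.586 in that order. Median and mean differ in sign for the YAP list (-0.07 and 0.01), the TGF-beta list (0.05 and -0.50) and the squamous list (0.31 and -1.03), whose camera directions were all down. The TGF-beta median turned to -0.0061 with upper-quartile scaling and to -0.061 after the GC and length correction. Of the 18 blood cell markers, 1 was measured, and it was called lower.

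Of 28 lists, 27 had at least 2 measured members and were tested, and 12 were called by camera at its preset correlation, 5 higher and 7 lower. With an estimated correlation, 0 lists passed (3 had an unadjusted p under 0.05), and fry called 21. The cholesterol list had an estimate of -0.004, below the preset value, yet its unadjusted camera p moved from 7.9e-11 to 0.002. Correlation between its members thus cannot account for that lost call. For the other lists called, estimates lay above the preset value, from 0.015 to 0.261. With an estimated correlation, camera also bases its p on the few residual degrees of freedom of the 6 libraries, which alone raises it. The endoplasmic reticulum list, with an estimate of 0.015, moved from an unadjusted camera p of 0.0178 to 0.0863. A call lost in this setting is therefore no measure of correlation alone. What correlation alone contributes to the lost calls of these lists was not tested.

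**Figure D4:**
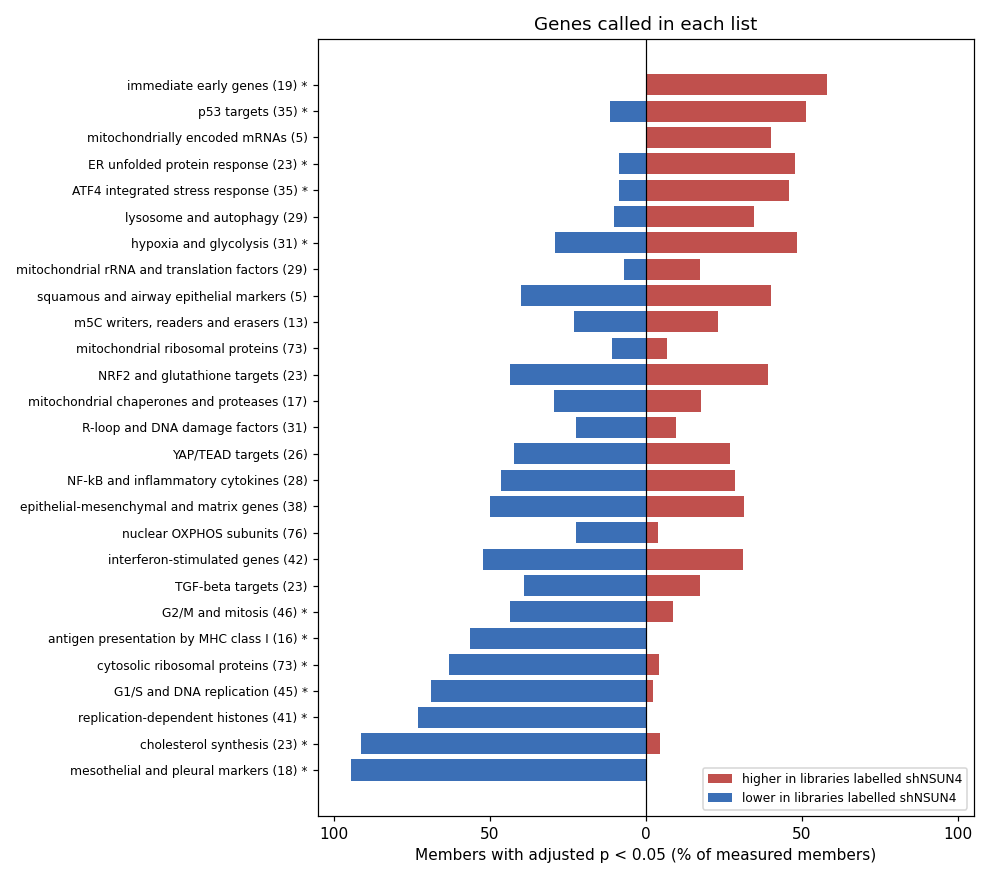
Share of measured members called higher (red, to the right) or lower (blue, to the left) in the libraries labelled shNSUN4, for the 27 lists tested, with the number of measured members in brackets. An asterisk marks the 12 lists called by camera at its preset correlation.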

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

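The GC and length correction, the thinning to equal depth, the matching by current symbol and the KEGG test were chosen after the data were seen. The 5114 genes called became 1406 with a minimum of a 2-fold change and 3142 when tested against a fold of 1.2, both stricter by construction. Every other setting named in the methods gave a count within 1.5 times, from 3885 (adjusted p under 0.01) to 5310 (replicate block), and from 4477 to 4795 without 1 library. The GC and length correction gave 4649, of which 3811 were called before in the same direction. The 12 lists called became 0 with an estimated correlation and 21 by fry, which tests another hypothesis. The lost calls are not all due to correlation between members, since the cholesterol list lost its call with an estimate below the preset value. That setting also bases p on far fewer degrees of freedom. Without 1 library, 10 to 13 lists were called. Upper-quartile scaling gave 2287 genes higher and 2891 lower, and library sizes alone 2547 and 2577. The log2 fold change of NSUN4 stayed between 0.33 and 0.72 over its alternatives and was called in none, with adjusted p from 0.277 to 0.669.

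With the replicate number as a block, 5310 genes and 10 lists were called; the endoplasmic reticulum list (adjusted p = 0.0813) and the hypoxia list (0.0698) were lost. Deviations of same-numbered libraries correlated at 0.0078, 0.0192 and -0.0048, where pairs of any numbers ran from -0.0271 to 0.0214. No signal shared by number was thus detected, but whether the samples were paired by design is not known from the labels. Of 132 genes taken by the rule, 9 lost their call in some setting and 0 turned direction. DHX30, MTRF1L, SFN and NSUN2 did so when 1 library was left out, and DHX30, MTRF1L, MRPL47, NDUFV1, NDUFS8, PHB2 and DDX21 after the GC and length correction. Alternatives planned for values other than counts were not run, since the table holds counts. In the simulation, at these depths and with 3 libraries per group, 18% of 1.25-fold changes were recovered. Far fewer genes were changed there than were called in the data, so this share may understate that in the data. What depth alone contributes was not tested in the simulation.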

Other observations

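Among the interferon-stimulated genes, 6 measured members known as direct targets of the transcription factor IRF3 were all called higher, with a median log2 fold change of 2.23: RSAD2, OASL, ISG15, IFIT2, IFIT3 and IFIT1. Of the other 36 members, 7 were called higher and 22 lower, with a median of -0.80. The 7 called higher had log2 fold changes from 0.29 to 2.79, a range that includes that of the IRF3 target IFIT1 (0.62). Among the 22 called lower were IRF7 (-1.94), a transcription factor of the interferon response, BST2 (-3.23) and IFITM1 (-3.61). This grouping was chosen after the values were seen, so it was not tested. Of the mesothelial markers, also picked after their values were seen, MSLN, CALB2 and WT1 had log2 fold changes of -1.06, -4.22 and -0.88. Of 241 KEGG pathways, 6 were called by camera and 0 with an estimated correlation (each at an adjusted p of 0.714); all 6 were lower. They were systemic lupus erythematosus and alcoholism, both of which hold histone genes, Staphylococcus aureus infection, steroid biosynthesis, DNA replication and ribosome.

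The tests of NSUN4 below were chosen after the result was seen; the tests of the genes and lists called were set before their results, although the trend with GC content was known. NSUN4 mRNA was not lower in the libraries labelled shNSUN4. A knockdown of at least 2-fold hidden by the low count is argued against, since the lower bound of the 95% interval of the fold was 0.733. Reads of an overlapping gene counted as NSUN4 are argued against only as far as GENCODE v29 goes, where 0 annotated genes overlap NSUN4. The annotation behind the counts is not known, and reads shared with other loci were not examined. An exchange of the labels of the 2 groups cannot be told apart from other causes: the 95% interval, which includes the spread between libraries, reaches a fold of 2.77, although counting error alone gives 1.048 to 1.898. A loss of protein without a loss of mRNA stays open and was not tested.

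The large number of genes called was weighed next. The lower depth of the libraries labelled shNSUN4 is argued against as the whole cause, since 4959 genes were called with every library thinned to the smallest total. GC content bias between the groups is argued against as the whole cause by the 4649 genes called after its correction, although 1293 genes lost their call in it and, of the genes called before, 116 changed sign, 10 of them called in the opposite direction. Regional copy number differences between 2 cell populations were tested on 101 blocks of 100 neighbouring genes. Of these, 17.8% lay outside the range of shuffled genes, where chance gives 5%. After the GC correction these blocks had a median shift of 0.14 and at most 0.21 on the log2 scale. Before it, the largest shift was 0.43, and the correction can itself take out regional shifts. The values argue only against large shifts of whole blocks that remain after the correction. Smaller shifts, smaller regions and differences in a part of the cells stay open. The 10 splits of the 6 libraries are too few for a share under 0.05. The real split called 5114 genes (1 of 10 splits as large) and the highest other 0. Every other split has both labels on each side, which adds the difference between the labels to the spread within its groups. Their 0 is thus no measure of chance. A library or culture batch that follows the labels, an effect of the shRNA other than on NSUN4, and an effect of NSUN4 cannot be separated with this design.

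The gene lists called were also weighed against GC content bias between the groups. All 12 were called in the same direction after the correction (14 lists in all, with lysosome and autophagy and R-loop and DNA damage factors gained), among which the mesothelial and cholesterol lists also passed with an estimated correlation (adjusted p = 0.0401 each). GC content bias is thus argued against as the whole cause for these 12 lists. Among the 10 splits of the libraries, the real split called 12 lists (1 of 10 splits as large) and the highest other 10. Every other split has both labels on each side, so part of the difference between the labels remains in it. The splits therefore cannot show how often camera calls lists where nothing differs, and they are too few for a share under 0.05.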
